A study of Mus musculus with 22 samples.

How the data were processed

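The deposited values are raw gene counts per library, in a table of 54532 genes for the 14 Pten libraries and a table of 56953 genes for the 8 Tsc2 libraries. Per the labels' protocols, RNA of the Pten cortex was extracted with TRIzol and sequenced from NEBNext Ultra II libraries as paired reads of 150 bp, and RNA of the Tsc2 frontal cortex was extracted with RNeasy and sequenced from Kapa Hyperprep libraries with polyA selection as single reads of 75 bp. Per the labels' protocols the authors aligned the reads with HISAT2, version 2.0.5 for the Pten libraries and a version not stated for the Tsc2 libraries. The tool that made the counts and the strandedness of the libraries are not given in the sources used here. The labels name GRCm39, but 53585 of the 54495 Pten genes with an identifier in the GRCm38 annotation had the same start and end there, so coordinates are printed as in the Pten table, as GRCm38. The Tsc2 table gives identifiers without names, of which 50989 were named through the Pten table. The names of 27 genes had been turned into dates in the Pten table and were restored from the identifiers.

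Groups were taken from the library titles. The genotype tag of the 2 libraries titled WT reads Het, and the design text gives 4 HET and 4 HOM animals where 6 and 6 libraries are present. No library was left out of the groups. The sex of each library was called from Xist and 4 Y-linked genes with at least 100 counts. Libraries of a group were checked for duplicates by the chi-square of their counts per degree of freedom, whose lowest value was 5.63 (range 5.63 to 33.7), so none was a copy. WT replicate 1 had 950 Y-linked counts beside Xist and stayed in.

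Counts of protein-coding genes (22046 in the Pten table, 21830 of them found in the Tsc2 table) were filtered with filterByExpr and scaled with TMM. Groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. HOM against HET was fitted on the 12 libraries, the comparisons with WT on all 14 Pten libraries, and KCplus against CCminus on the 8 Tsc2 libraries. The difference of the effects was a contrast in 1 fit of 4 groups over both tables. CPM used TMM library sizes, and the levels of Pten and of the WT comparisons came from the fit of 14 libraries. The SE of a log2 change was derived from the fit. Genes called in both models were counted per direction beside the product of both counts divided by the number of genes tested in both. The correlation between models was tested over all 70 relabellings of the Tsc2 libraries.

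The 34 gene lists were written before the data were examined, as were the named-gene rule, the models and the main alternatives. The lists hold PI3K-AKT-mTOR components, FOXO targets, cholesterol and fatty acid synthesis, lysosome, ATF4 response, glycolysis, ribosomal proteins, oxidative phosphorylation, markers of the brain's cell types and regions, glial reaction, immediate early genes, neuropeptides, receptors, channels, extracellular matrix, autism-associated genes, interferon response and cell cycle. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The mean of a list per library was compared by exact permutation after the camera results were seen. Named genes were the targeted gene, the 10 higher and 10 lower called genes with the smallest p-values at a mean log2 CPM of at least 1 (5 and 5 for the comparisons with WT and between models), and up to 4 members of each list with the smallest p-values.

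Alternatives were RLE size factors, no filter, all gene classes, DESeq2 1.42.0, 1 surrogate variable (sva 3.50.0), limma voom, a fold of at least 1.5, each library left out in turn, the replicate number as a block, a sex term, the WT libraries counted with HET, and a fit of all 14 libraries. Female libraries only, and the sex term for the lists, the named genes and the comparison of models, were added after the sex make-up was seen. The method was tested on simulated counts with 100 genes changed 1.5-fold and 100 changed 2-fold. It found 64 and 80 of them for HOM against HET (14265 genes), 47 and 82 for HET against WT (14883), 52 and 82 for HOM against WT (14883), 79 and 95 for KCplus against CCminus (13848) and 36 and 87 for the difference (14580), calling 7, 4, 5, 14 and 8 unchanged genes. A list raised 1.25-fold in simulated Tsc2 counts (13848 genes) had adjusted p = 1.13e-40 and 0.000141 with an estimated correlation, with 0 of the 33 other lists passing under either. The simulated genes were drawn independently of each other. The simulation therefore does not test how often lists of correlated genes pass falsely at the preset correlation. Coexpression networks, annotation enrichment and an autism gene database are named in the design text and were not analysed here.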

Results

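RNA from the cortex of mice of 2 models was sequenced. In the Pten model, whose series title names a knockout restricted to neurons, the titles gave 6 heterozygous (HET), 6 homozygous (HOM) and 2 wild-type (WT) libraries of cortex at postnatal day 45. In the Tsc2 model, frontal cortex at postnatal day 30 gave 4 mutant (KCplus) and 4 control (CCminus) libraries. Pten and Tsc2 encode negative regulators of the PI3K-AKT-mTOR pathway, and the question was which genes change with loss of each and whether the models share them. The total per library was 17859602 ± 466578 counts in HET (SD, n = 6, range 17410981 to 18621342), 17487384 ± 1446764 in HOM (n = 6, 14733320 to 18619642) and 17295310 ± 2867221 in WT (n = 2, 15267879 to 19322742). It was 20138322 ± 1814589 in CCminus (n = 4, 18365289 to 22429226) and 21819998 ± 2214037 in KCplus (n = 4, 20289736 to 25097344). By the counts of Xist and 4 Y-linked genes, all 6 HET libraries were female, HOM held 3 male (replicates 1, 4 and 6) and 3 female libraries, CCminus 1 male and 3 female, and KCplus 2 male and 2 female. WT replicate 2 was male and WT replicate 1 carried both Xist and Y-linked counts. The labels do not say that each library came from a separate animal, and the design text gives 4 HET and 4 HOM animals, fewer than the libraries. The p-values therefore measure only the spread between libraries.

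Pten itself (ENSMUSG00000013663, GRCm38 chromosome 19, 32757497 to 32826160), a lipid phosphatase that opposes PI3K, did not pass in any comparison of the Pten model. Its level was 169 ± 8.48 CPM (counts relative to the library size) in HOM (SD, n = 6), 182 ± 10.9 in HET (n = 6) and 205 ± 3.30 in WT (n = 2), a log2 change of -0.12 ± 0.0546 (SE) for HOM against HET (adjusted p = 0.225) and -0.28 ± 0.0733 for HOM against WT (adjusted p = 0.144). The counts cover the whole gene and the deleted exons are not given in the sources used here, so this level checks the genotype labels only in part. Tsc2 (ENSMUSG00000002496, GRCm38 chromosome 17, 24595816 to 24632630), part of the complex that holds mTORC1 back, fell from 96.0 ± 1.56 CPM in CCminus to 60.1 ± 2.55 in KCplus (n = 4 each, log2 change -0.67 ± 0.0450, adjusted p = 2.77e-05). All 4 KCplus libraries (56.4 to 62.0) lay below all 4 CCminus libraries (94.8 to 98.2). Tsc2 was at 109 ± 7.45 in HOM and 105 ± 4.25 in HET (adjusted p = 0.665). Pten rose from 282 ± 16.5 in CCminus (268 to 305) to 347 ± 35.4 in KCplus (307 to 382), a log2 change of 0.30 ± 0.0732 (adjusted p = 0.0203).

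**Figure D1:**
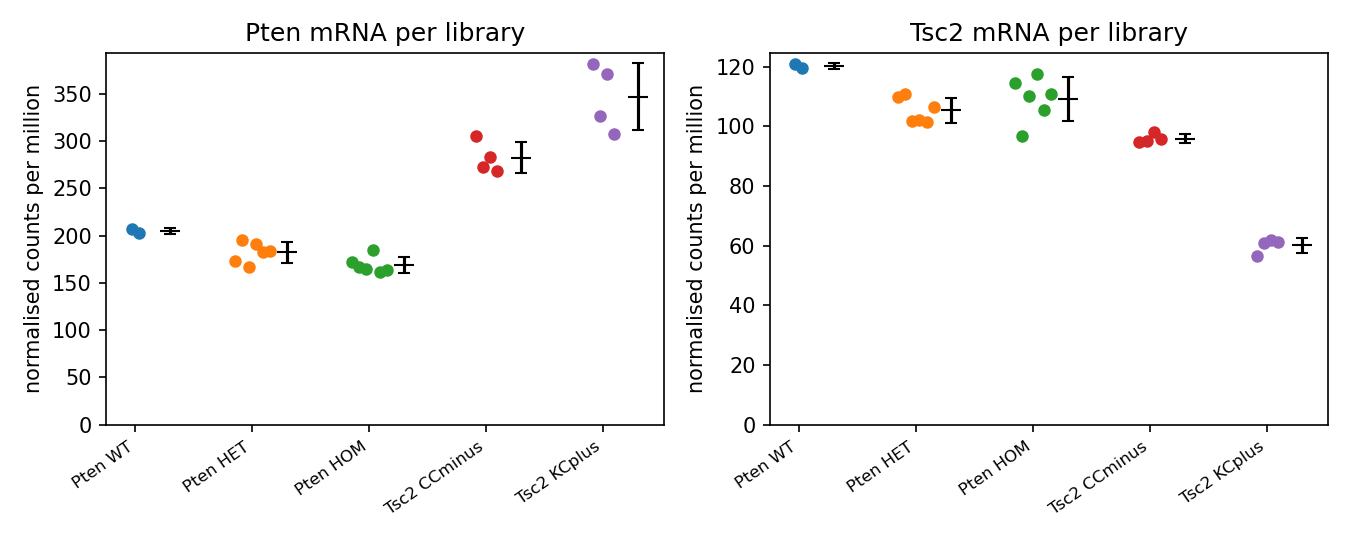
CPM of Pten and Tsc2 in each library (points) of each group, with the mean and SD as bars. Tsc2 lies between 56.4 and 62.0 in the 4 KCplus libraries and between 94.8 and 98.2 in the 4 CCminus libraries.

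Between HOM and HET cortex, genes of sterol synthesis rose and Rgs11, a regulator of G protein signalling, fell the most surely among lower genes. Sqle (ENSMUSG00000022351, chromosome 15, 59315077 to 59331192), which makes the first oxygenated sterol precursor, rose 1.57-fold from 68.9 ± 3.10 to 108 ± 10.4 CPM (SD, n = 6 each, log2 change 0.65 ± 0.0621, adjusted p = 0.000417). Dhcr24, Dhcr7, Cyp51 and Hmgcr, further enzymes of the same pathway, rose by log2 0.60, 0.53, 0.53 and 0.46, and Aacs, which feeds acetoacetate into lipid synthesis, by 0.48. S100b (ENSMUSG00000033208, chromosome 10, 76253853 to 76261159), a calcium-binding protein of glia, rose 1.71-fold from 124 ± 8.26 to 212 ± 37.4. The transporter Slco3a1 rose by log2 0.61, the neurexin ligand Nxph1 by 0.57 and the stress sensor Sesn2 by 0.49. Rgs11 (ENSMUSG00000024186, chromosome 17, 26202951 to 26211324) fell 1.91-fold from 29.5 ± 4.82 to 15.4 ± 1.69 (log2 change -0.93 ± 0.109, adjusted p = 0.000996). Leng8 had a log2 change of -0.74, the presynaptic scaffold Tspoap1 -0.57, the RNA-binding Tia1 -0.51, Zkscan3 -0.49, Eml5 -0.47, the phosphatase Dusp26 -0.46, Ubn2 -0.46, Zscan26 -0.43 and Plekha5 -0.36. These 20 genes passed at an adjusted p of 0.00300 or lower.

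In total 871 of 14358 protein-coding genes passed in edgeR (384 higher, 487 lower), of which 180 changed at least 1.5-fold (109 higher, 71 lower). The same test gave 108 genes with a sex term and 56 in female libraries only (3 HOM against 6 HET), while the log2 changes of Sqle (0.71 and 0.72), S100b (0.83 and 0.84) and Rgs11 (-0.95 and -0.94) stayed called under both. All 6 HET libraries were female, so the sex term too sets only the 3 female HOM libraries against HET. These fits are therefore not separate checks. Their lower counts come with fewer HOM libraries in the contrast and do not show that the other genes were due to sex. Without HET replicate 3 the count was 396, without HOM replicate 3 it was 413, without HOM replicate 1 437, without HET replicate 5 470 and without HET replicate 2 538.

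Of the 34 measured genes of cholesterol and fatty acid synthesis, 21 rose, 0 fell and 13 did not pass, with a median log2 change of 0.35, and 28 rose adjusted over the list alone. The list passed camera at adjusted p = 7.39e-22, and at adjusted p = 0.00239 with an estimated correlation. The mean of the list lay 0.28 to 0.45 above the HET mean in the 6 HOM libraries, against -0.05 to 0.06 in the 6 HET libraries. It was the 1 list of the 12 that passed in this comparison to hold with an estimated correlation, and it also passed in female libraries only (adjusted p = 1.56e-19, 13 genes higher). Female HOM libraries differed from HET by 0.36 ± 0.0817 (SD, n = 3) and male ones by 0.33 ± 0.0286 (n = 3), each with a two-sided exact permutation p of 0.0119, the smallest possible.

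**Figure D2:**
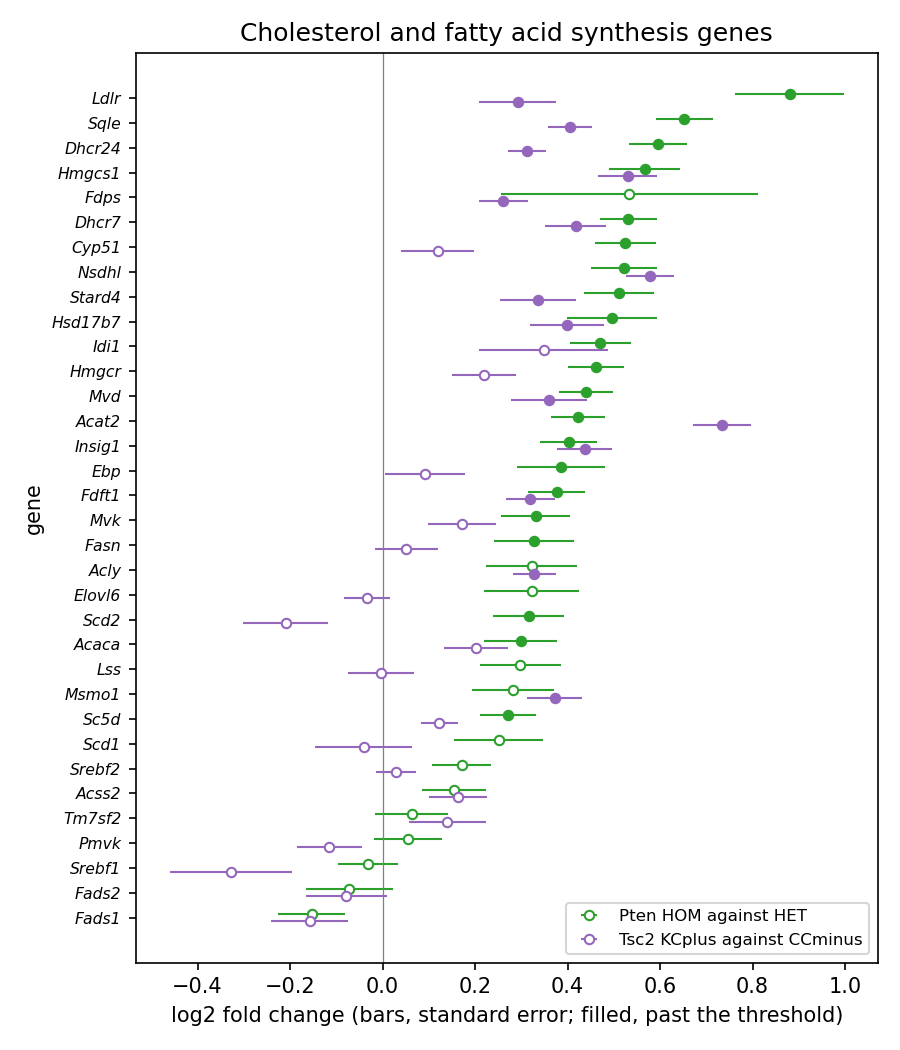
Log2 change of each measured gene of cholesterol and fatty acid synthesis in the Pten model (HOM against HET) and in the Tsc2 model (KCplus against CCminus), with SE bars and filled points for genes past the threshold. The median log2 change of the list is 0.35 in the Pten model and 0.21 in the Tsc2 model.

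Ribosomal protein genes were lower in HOM than in HET. Of 77 measured, 0 rose, 20 fell and 57 did not pass (median log2 change -0.21, 48 lower adjusted over the list alone). The list had 0 and 0 genes lower with a sex term and in female libraries only (13 and 9 lower adjusted over the list alone). Rps21 had a log2 change of -0.42 ± 0.0754, Rps8 -0.32, Rps23 -0.31 and Rpl27a -0.30. The list passed at adjusted p = 1.31e-16, and had adjusted p = 0.427 with an estimated correlation. Genes of this class can share reads with pseudogenes, which was not measured here, so each value is uncertain. The mitochondrial share of protein-coding counts was lower in HOM (4.38% ± 0.470) than in HET (5.48% ± 0.748, n = 6 each, two-sided exact permutation p = 0.00866). It was 4.69% ± 0.607 in WT (n = 2), nearer to HOM, so whether HOM stood low or HET high stays open. All HET libraries were female, which this test did not account for. Genes of oxidative phosphorylation had a median of 0.07, with 2 of 67 higher (Cyc1 0.20, Ndufa3 0.16), 0 lower and 65 not passing, and 0 adjusted over the list alone (adjusted p = 0.000542, adjusted p = 0.567 with an estimated correlation). Here 0 and 0 rose with a sex term and in female libraries only.

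Some markers of oligodendrocytes and of glial reaction rose. Of 28 myelin genes, 8 rose and 0 fell (13 higher adjusted over the list alone, median 0.45), among them the protease Klk6 at log2 2.12 ± 0.341, the actin-severing Gsn at 1.34 ± 0.178, the gap junction gene Gjb1 at 1.02 and the lipid hydroxylase Fa2h at 0.74. The list had adjusted p = 1.23e-06, adjusted p = 0.659 with an estimated correlation, and its mean per library did not separate the groups (two-sided exact permutation p = 0.0563, n = 6 each). Of 15 oligodendrocyte precursor genes, 5 rose and 0 fell (8 higher adjusted over the list alone, median 0.28), with Enpp6 at 0.84, Gpr17 at 0.65, C1ql1 at 0.52 and the transcription factor Olig1 at 0.42 (adjusted p = 0.000235, adjusted p = 0.427 with an estimated correlation). Of 26 reactive astrocyte genes, 5 rose and 0 fell (8 higher and 1 lower adjusted over the list alone, median 0.16), with the adhesion receptor Cd44 at 1.06, Serpina3n at 1.05, the complement gene C4b at 0.93 and the intermediate filament Gfap at 0.93 ± 0.167 (adjusted p = 0.000985, adjusted p = 0.567 with an estimated correlation). Of 21 disease-associated microglia genes, 3 rose and 0 fell (7 higher adjusted over the list alone, median 0.31), namely the secreted Spp1 at 0.76, Lgals3bp at 0.64 and the lysozyme Lyz2 at 0.61, while Gpnmb had 1.01 and did not pass (adjusted p = 0.000542, adjusted p = 0.148 with an estimated correlation). Of 38 lysosomal genes, 2 rose and 0 fell (5 higher adjusted over the list alone, median 0.13), with Grn at 0.39 and Npc2 at 0.28 (adjusted p = 0.000235, adjusted p = 0.148 with an estimated correlation). Of these lists, 2 and 2 myelin, 0 and 0 precursor, 0 and 2 reactive astrocyte, 1 and 0 microglia and 1 and 1 lysosomal genes rose with a sex term and in female libraries only.

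The neurofilament genes Nefh and Nefm and some interneuron genes rose. Of 23 pan-neuronal genes, 4 rose and 0 fell (5 higher adjusted over the list alone, median 0.14), namely the neurofilaments Nefh at 1.11 ± 0.168 and Nefm at 0.80 ± 0.107, the vesicle protein Syn2 at 0.55 and the tubulin Tubb3 at 0.45 (adjusted p = 0.000542, adjusted p = 0.398 with an estimated correlation). Of 35 interneuron genes, 3 rose and 1 fell (9 higher and 1 lower adjusted over the list alone, median 0.27), with the secreted Reln at 0.61, the transcription factor Arx at 0.44, the GABA transporter Slc6a1 at 0.42 and the peptide gene Cort at -0.88 (adjusted p = 8.91e-05, adjusted p = 0.148 with an estimated correlation). Of 26 genes of the extracellular matrix, 3 rose and 0 fell (6 higher adjusted over the list alone, median 0.08), including Timp2 at 0.35 and Ncan at 0.25. That list had adjusted p = 0.0258, adjusted p = 0.567 with an estimated correlation, and 0.0841, 0.0524 and 0.128 without HET replicates 1, 4 and 6. Of 20 endothelial genes, 0 rose and Sox17 fell, with a log2 change of -0.92 (median -0.22). Their adjusted p was 0.00116, adjusted p = 0.730 with an estimated correlation, 0.155 with a sex term and 0.0661 in female libraries only. With that term and in female libraries only, 3 and 2 pan-neuronal genes rose. For interneuron, matrix and endothelial genes 0 passed under either.

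The other 22 lists did not pass (adjusted p from 0.0557 to 0.928). Of these, 4 passed with a sex term and in female libraries only. They were immediate early genes, lower (adjusted p = 0.00788 and 0.00579), cell cycle genes, higher (0.0101 and 0.00777), interferon genes, higher (0.0219 and 0.00750), and choroid plexus genes, lower (0.0294 and 0.0116). With an estimated correlation they had adjusted p = 0.690, 0.613, 0.613 and 0.613 with the sex term and 0.697, 0.442, 0.549 and 0.577 in females. In the PI3K-AKT-mTOR list 0 of 44 genes rose and 2 fell, the kinase Rps6kb2 at log2 -0.47 and the receptor Igf1r at -0.32, and of the FOXO targets Ccng2 (-0.26) and Cdkn1b (-0.23) fell. In the ATF4 list Sesn2 rose while Atf5 (-0.34) and Phgdh (-0.33) fell, and in the glycolysis list Pgam1 (0.33), Pkm (0.25) and Tpi1 (0.24) rose while Vegfa (-0.31) fell. Among the remaining lists, the peptide gene Pnoc (0.62), the receptors Grin3a (0.62) and Grm1 (0.41), the channel partner Kcnip1 (0.70) and the microglial Fcrls (0.36) rose. Egr3 (-0.37), Gria2 (-0.19), Kcnh3 (-0.28) and, of the autism list, Phip (-0.25) fell. The autism list had 4 of 70 genes higher and 1 lower, and microglia markers and astrocyte markers each had 1 higher and 0 lower. Excitatory neuron, mural, choroid plexus, blood, GABA receptor, sodium and calcium channel, interferon, cell cycle, striatal, hippocampal and thalamic lists had 0 genes past the edgeR threshold. The median, mean and test differed in sign for mural, GABA receptor, autism, striatal and hippocampal genes.

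Against the 2 WT libraries, 0 of 15010 genes passed in edgeR for HET and 13 for HOM (4 higher, 9 lower). In HET the unadjusted p was under 0.05 for 367 genes, DESeq2 called 4 (Rps21, higher, and the Y-linked Ddx3y, Eif2s3y and Kdm5d, lower, where all HET libraries were female), and in edgeR Rps21 at log2 0.53 and Ndufa3 at 0.30 had adjusted p = 0.829, the lowest reached. In HOM the subunit Ndufa3 rose from 52.7 ± 1.44 to 72.6 ± 3.13 CPM (SD, n = 2 and 6, log2 change 0.46 ± 0.0611, adjusted p = 0.0183), and Slco3a1 rose by 0.65, the carrier Slc25a10 by 0.62 and Dhcr7 by 0.57. Rgs11 had a log2 change of -1.01, Eml5 -0.53, Zscan26 -0.47, Plekha5 -0.46 and the deubiquitinase Otud4 -0.40 (adjusted p = 0.0289 each). The 13 genes became 0 without HOM replicate 1 or WT replicate 1, 1 without HOM replicate 3 (Ndufa3), 2 without HET replicate 4 (Ndufa3, Slco3a1), HOM replicate 6 (Ndufa3, S100b) or WT replicate 2 (Rgs11, Leng8), 8 without HET replicate 3, 24 without HOM replicate 4 and 37 without HOM replicate 2. DESeq2 called 255 genes, and Ndufa3 alone passed with a sex term.

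Cholesterol genes were higher in HOM than in WT as a list (median 0.25, 1 higher, 15 adjusted over the list alone, adjusted p = 3.52e-14, adjusted p = 0.0257 with an estimated correlation). Another 8 lists passed for HOM, none of which held with an estimated correlation, where their adjusted p ran from 0.0993 to 0.804. These were oxidative phosphorylation (median 0.17, adjusted p = 1.59e-13), lysosomal (0.10, 0.000164), oligodendrocyte precursor (0.33, 0.000162), disease-associated microglia (0.35, 0.000111), microglia (0.27, 9.28e-05), interneuron (0.26, 0.000989), myelin (0.30, 0.00245) and, lower, immediate early genes (-0.34, 9.28e-05). Without WT replicate 1 microglia had adjusted p = 0.272 and interneuron genes 0.0995, and myelin had 0.0562 without HOM replicate 5 and 0.330 without WT replicate 2. Ribosomal protein genes did not pass for HOM (median 0.03, adjusted p = 0.164) and were higher in HET than in WT (median 0.25, adjusted p = 3.08e-38, adjusted p = 0.495 with an estimated correlation). The 11 lists past the camera threshold for HET against WT, 0 of which held with an estimated correlation (adjusted p from 0.495 to 0.878), also included oxidative phosphorylation (0.09, 2.53e-08), cholesterol (-0.10, 0.00138), microglia (0.18, 0.000144), immediate early (-0.18, 0.000231) and autism genes (-0.05, 0.00988). Astrocyte (0.12, 0.0217), endothelial (0.16, 0.0219), pan-neuronal (-0.07, 0.0219), potassium channel (-0.05, 0.0219) and myelin genes (-0.11, 0.0321) completed them. Without WT replicate 1 the adjusted p was 0.928 for cholesterol, 0.967 for microglia, 0.772 for astrocyte, 0.351 for endothelial, 0.325 for pan-neuronal, 0.154 for potassium channel and 0.0553 for autism genes. Myelin reversed without it (0.949) and had 0.380, 0.282 and 0.313 without HET replicates 1, 3 and 5. Without HET replicate 3 astrocyte genes had 0.121 and endothelial 0.117. Without HET replicate 5 astrocyte had 0.404, endothelial 0.204, pan-neuronal 0.106, potassium channel 0.222 and autism genes 0.0551. Immediate early genes had 0.0521 without HET replicate 2, and pan-neuronal genes 0.0683 without HET replicate 4. Autism genes had 0.0540 without HET replicate 6 and 0.108 without WT replicate 2, and potassium channel genes 0.133 without the latter. All HET libraries were female, and neither WT library was called female. With a sex term the adjusted p was 0.105 for pan-neuronal, 0.299 for potassium channel, 0.375 for immediate early and 0.953 for autism genes. Endothelial genes reversed (0.985).

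In the frontal cortex of the Tsc2 model, Mybpc1, Tfrc and Bche rose and, besides Tsc2, Cdk19, Opalin and Mcam fell. Mybpc1 (ENSMUSG00000020061, chromosome 10, 88518279 to 88605152), a myosin-binding protein known from muscle, rose 4.77-fold from 4.39 ± 0.635 to 20.95 ± 1.77 CPM (SD, n = 4 each, log2 change 2.25 ± 0.108, adjusted p = 3.71e-06). Tfrc (ENSMUSG00000022797, chromosome 16, 32608920 to 32632794), the receptor for iron-loaded transferrin, rose 2.56-fold from 123 ± 3.87 to 315 ± 48.5 (log2 change 1.36 ± 0.0926, adjusted p = 2.85e-05). Asb2 rose by log2 1.65, the cholinesterase Bche by 1.53, the imprinted Peg10 by 1.30, Arid5a by 1.26, the scaffold Whrn by 1.01, Trnp1 by 0.78, the PI3K subunit Pik3r3 by 0.69 and the kinase Map3k9 by 0.63. Opalin (ENSMUSG00000050121, chromosome 19, 41062474 to 41077113), an oligodendrocyte membrane protein, fell from 23.04 ± 2.13 to 8.47 ± 1.45 (log2 change -1.44 ± 0.118, adjusted p = 5.53e-05). Cdk19 (ENSMUSG00000038481, chromosome 10, 40339564 to 40483818), a kinase of the Mediator complex, fell from 116 ± 5.17 to 73.9 ± 1.82 (log2 change -0.66). Rnf122 had a log2 change of -1.41, the adhesion gene Mcam -1.14, Tspan2 -0.89, Vstm2l -0.76, Sept4 -0.71, the ephrin receptor Ephb1 -0.67 and the motor Kifc2 -0.59.

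In total 2232 of 13927 genes passed in edgeR (1137 higher, 1095 lower), of which 353 changed at least 1.5-fold (199 higher, 154 lower). Female libraries only (2 against 3) gave 1072 genes, 990 of them among the 2232. Without KCplus replicate 3 the count was 1363, without CCminus replicate 3 it was 1394, and without KCplus replicate 4, of whose counts 3.20% fell on ENSMUSG00000119584, it was 1913.

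Lysosomal and amino acid response genes rose in KCplus. Of 38 lysosomal genes 21 rose and 1 fell (22 higher and 1 lower adjusted over the list alone, median 0.23). Among them were the glycosidases Gla at log2 0.91 ± 0.0942, Neu1 at 0.56 and Gba at 0.48, and also Gns at 0.35. This list passed at adjusted p = 1.11e-08 and was the 1 list of the 15 passing to hold with an estimated correlation (adjusted p = 0.0140). It did not hold so in female libraries only (adjusted p = 6.89e-07, adjusted p = 0.288 with an estimated correlation). Its mean lay 0.20 to 0.23 above the CCminus mean in the 4 KCplus libraries. Of 32 genes of the ATF4 response 16 rose and 2 fell (19 higher and 5 lower adjusted over the list alone, median 0.23), with the amino acid transporter Slc7a3 at 1.76 ± 0.203, Sesn2 at 1.02, the synthetase Asns at 0.59 and Nars at 0.47 (adjusted p = 3.78e-05, adjusted p = 0.537 with an estimated correlation). Of 34 cholesterol genes 15 rose and 0 fell (20 higher and 1 lower adjusted over the list alone, median 0.21), with Acat2 at 0.73, Nsdhl at 0.58, Hmgcs1 at 0.53 and Sqle at 0.40 ± 0.0474 (adjusted p = 3.07e-07, adjusted p = 0.122 with an estimated correlation). The microglial and lysosomal gene Gpnmb rose by 2.38 ± 0.225, while Cd9 (-0.55), Axl (-0.44) and Csf1 (-0.44) of the same disease-associated microglia list fell, and that list did not pass (adjusted p = 0.904).

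Myelin and ribosomal protein genes fell. Of 28 myelin genes 0 rose and 21 fell (1 higher and 22 lower adjusted over the list alone, median -0.72), with Opalin at -1.44, the receptor Gpr37 at -0.93, Tspan2 at -0.89 and the tight junction gene Cldn11 at -0.83 ± 0.0754 (adjusted p = 3.83e-12, adjusted p = 0.537 with an estimated correlation). Of 15 oligodendrocyte precursor genes 0 rose and 5 fell (5 lower adjusted over the list alone, median -0.29), with Bcas1 at -0.95, Enpp6 at -0.74, Sox10 at -0.54 and Cspg5 at -0.33 (adjusted p = 0.000239, adjusted p = 0.599 with an estimated correlation). Of 77 ribosomal protein genes, whose values are uncertain for the same reason as in the Pten model, 0 rose and 55 fell (61 lower adjusted over the list alone, median -0.30), with Rps27 at -0.62, Rps14 at -0.53, Rpl17 at -0.51 and Rps7 at -0.34 (adjusted p = 1.16e-18, adjusted p = 0.548 with an estimated correlation). The mitochondrial share of protein-coding counts was 5.54% ± 0.719 in KCplus and 5.85% ± 0.591 in CCminus (n = 4 each, two-sided exact permutation p = 0.571). Of 22 astrocyte genes 0 rose and 7 fell (8 lower adjusted over the list alone, median -0.25), including Gpc5 (-0.41), F3 (-0.40), the glutamate transporter Slc1a2 (-0.34) and S100b (-0.27), and of 26 microglia genes Gpr34 (-0.33) and P2ry12 (-0.30) fell (0 adjusted over the list alone, median -0.28). Their adjusted p was 0.000526 and 0.000239, adjusted p = 0.680 for both with an estimated correlation. Of these markers 4 and 5 astrocyte and 0 and 4 microglia genes fell with a sex term and in female libraries only.

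Of 23 pan-neuronal genes 8 rose and 2 fell (10 higher and 3 lower adjusted over the list alone, median 0.12), with Nefm at log2 1.02 ± 0.138, Syn2 at 0.77, Nefh at 0.75 and Tubb3 at 0.46. Of 35 interneuron genes 10 rose and 2 fell (14 higher and 3 lower adjusted over the list alone, median 0.19), with Cort at 1.77 ± 0.227, somatostatin (Sst) at 0.71, and the GABA-synthesising Gad1 at 0.48 and Gad2 at 0.44. Of 27 neuropeptide and granule genes 11 rose and 4 fell (12 higher and 6 lower adjusted over the list alone, median 0.19), with Adcyap1 at 0.93, Scg2 at 0.78 and Vgf at 0.51. These lists had adjusted p = 0.0103, 0.00462 and 0.0121, adjusted p = 0.680, 0.680 and 0.537 with an estimated correlation, and in female libraries only 0.0874, 0.0874 and 0.113. Neuropeptide genes had 0.0506 without CCminus replicate 1. In females 5 interneuron genes rose and 1 fell. Of 24 glutamate receptor genes 0 rose and 6 fell (6 lower adjusted over the list alone, median -0.02), with Grin2d at -0.61, Grik4 at -0.52, Grm2 at -0.28 and Grid2 at -0.25. Their adjusted p was 0.0291, adjusted p = 0.325 with an estimated correlation, 0.0754 in female libraries only, and 0.0715, 0.0630 and 0.0583 without CCminus replicate 1, CCminus replicate 4 and KCplus replicate 4.

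Of 70 autism-associated genes 3 rose and 16 fell (4 higher and 19 lower adjusted over the list alone, median -0.08), with Hivep2 at -0.35, the methyltransferase Ash1l at -0.33, Iqsec2 at -0.30 and Med13l at -0.27 (adjusted p = 0.000765, adjusted p = 0.325 with an estimated correlation). Of 27 cell cycle genes 3 rose and 0 fell (3 higher adjusted over the list alone, median 0.29), namely Ccna2 at 0.84, Kif11 at 0.49 and Tpx2 at 0.45 (adjusted p = 0.000889, adjusted p = 0.599 with an estimated correlation). Of 67 oxidative phosphorylation genes 8 rose and 0 fell (4 higher adjusted over the list alone, median 0.06), including Atp5g1 (0.28), Cyc1 (0.22) and Ndufa10 (0.21). That list had adjusted p = 0.00271, adjusted p = 0.680 with an estimated correlation, 0.434 in female libraries only and 0.0602 without KCplus replicate 2. Of its genes 4 rose with a sex term. In females 0 of them and 0 cell cycle genes rose, and of the autism list 1 rose and 8 fell. The other 19 lists did not pass (adjusted p from 0.0692 to 0.904). Of these, choroid plexus genes, higher, passed with a sex term (adjusted p = 0.0429, adjusted p = 0.366 with an estimated correlation) and in female libraries only (0.0132, and 0.556 with it). Excitatory neuron genes, lower, passed with a sex term (adjusted p = 0.0261, adjusted p = 0.697 with an estimated correlation). Among the immediate early genes 7 of 35 rose and 0 fell, including the growth factor Bdnf at 0.83, the synaptic Nptx2 at 0.80, Gadd45g at 0.58 and Jun at 0.57. Of 44 PI3K-AKT-mTOR genes 2 rose and 9 fell (3 higher and 12 lower adjusted over the list alone), with Tsc1 at 0.28, Foxo3 at -0.41, the phosphatase Phlpp1 at -0.39 and Igf1r at -0.35. Of the FOXO targets 3 rose and 2 fell, with Erbb3 at -0.99, Irs2 at -0.38 and Sesn3 at 0.27.

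Of 31 excitatory neuron genes 1 rose, the vesicular transporter Slc17a7 (0.32), and 7 fell, including Otof (-0.84), the kinase Camk2a (-0.49) and Calb1 (-0.39). Of 56 potassium and HCN channel genes 7 rose and 5 fell, with Hcn3 at 0.56, Kcnj4 at 0.46 and Kcnh3 at -0.49, and of 26 sodium and calcium channel genes 0 rose and 4 fell, with Cacna1g at -0.40 and Cacnb3 at -0.28. Glycolysis genes had 6 higher and 2 lower, with Pkm at 0.35, Pgk1 at 0.33 and the oxygen sensor Egln1 at -0.37. Gabrd (0.27) rose and Gabrb1 (-0.29) fell among the GABA receptor genes, and Adamts1 (0.68) and Col4a1 (0.38) rose in the matrix list. Sphk1 (0.63) and Serpina3n (0.22) of the reactive astrocyte list rose, as did Ifit2 (0.61) of the interferon list, Tac1 (0.43) of the striatal list and the ciliary factor Foxj1 (0.95) of the choroid plexus and ependymal list, while its marker Ttr had 2.90 ± 1.30 and did not pass. Bpgm (-0.16) of the blood list, Prox1 (-0.25) of the hippocampal list and Tcf7l2 (-0.60) and Ramp3 (-0.56) of the thalamic list fell. The endothelial and mural lists had 0 genes past the edgeR threshold. The median, mean and test differed in sign for disease-associated microglia, immediate early, sodium and calcium channel and hippocampal genes.

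**Figure D3:**
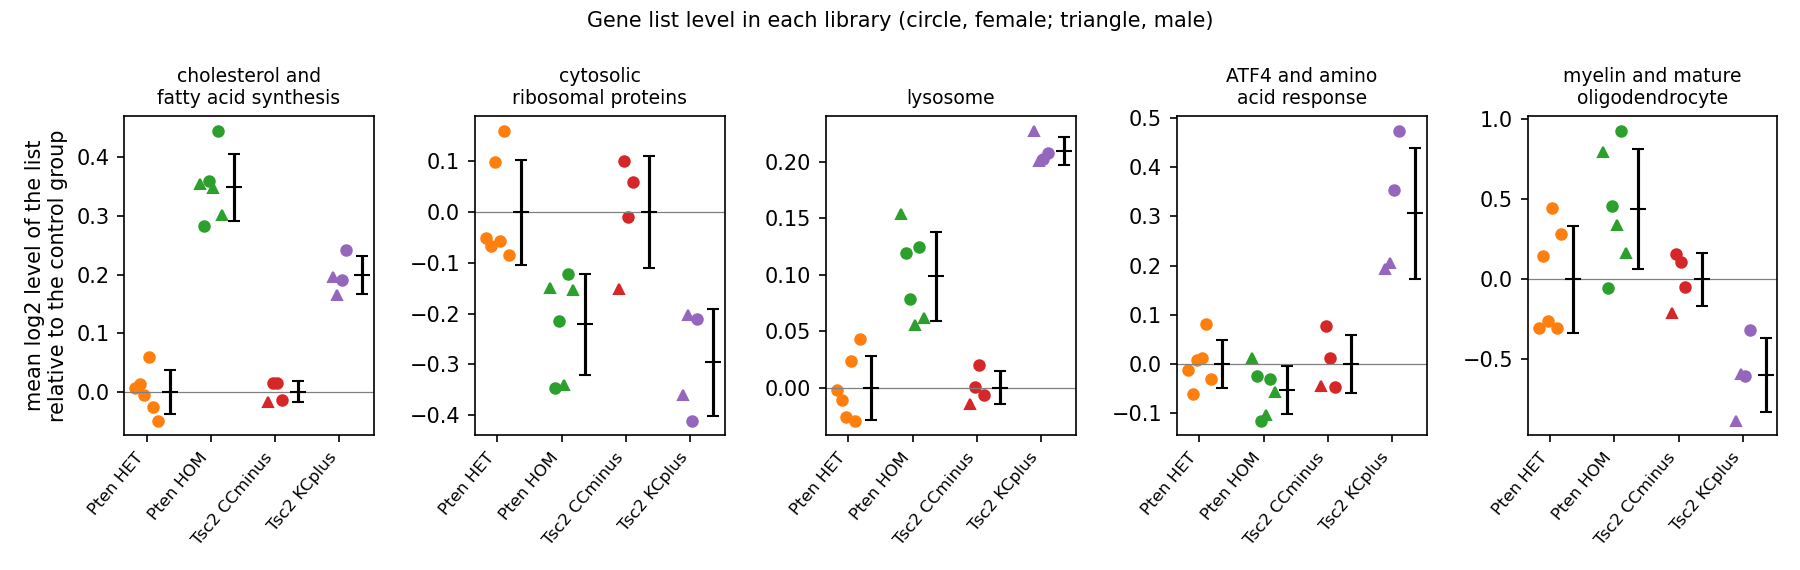
Mean log2 level of gene lists in each library, relative to HET in the Pten model and to CCminus in the Tsc2 model, with points for libraries and bars for group means. The cholesterol list lies between 0.28 and 0.45 in HOM and between 0.16 and 0.24 in KCplus.

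The models shared called genes of sterol synthesis and, over all libraries without a sex term, of the ribosome. Among 13775 genes tested in both, 139 were higher in both where 30.9 would be shared by chance, and 68 were lower in both (37.4 by chance), while 24 were higher in Pten HOM and lower in Tsc2 KCplus (29.9 by chance) and 15 the reverse (38.7 by chance). The genes higher in both included 12 of cholesterol synthesis, such as Sqle, Nsdhl and Hmgcs1, the pan-neuronal Syn2, Tubb3, Nefm and Nefh, and 3 glycolysis genes, and those lower in both included 18 ribosomal protein genes. None of these 18 was called lower in HOM with a sex term or in female libraries only. Both fits set only 3 HOM libraries against HET. The mean of the ribosomal list differed from HET by -0.23 in the 3 female and by -0.21 in the 3 male HOM libraries. The loss of these calls thus does not show an effect of sex. Opposite were 4 myelin and 2 oligodendrocyte precursor genes (higher in HOM, lower in KCplus), S100b (0.78 in HOM, -0.27 in KCplus) and Cort (-0.88 and 1.77). The number shared in the same direction, 207, was 98 without HET replicate 3, 108 without HOM replicate 3, 116 without HET replicate 5, 116 without HOM replicate 1, 37 with a sex term and 17 in female libraries only. Across genes, which are not independent replicates, the log2 changes had a Pearson r of 0.195 and a Spearman rho of 0.230. On differences of mean log2 CPM r was 0.210, as large in size in 6 of the 70 relabellings of the Tsc2 libraries (two-sided exact permutation p = 0.0857, smallest possible 0.0286). The Pearson value thus did not hold up. The same exact permutation gave p = 0.0286 on ranks and without HET replicate 6 (r = 0.222). In female libraries only r was 0.111 (exact permutation p = 0.3). There the 2 KCplus and 3 CCminus libraries allow too few relabellings for any p under 0.05, so this p decides nothing.

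**Figure D4:**
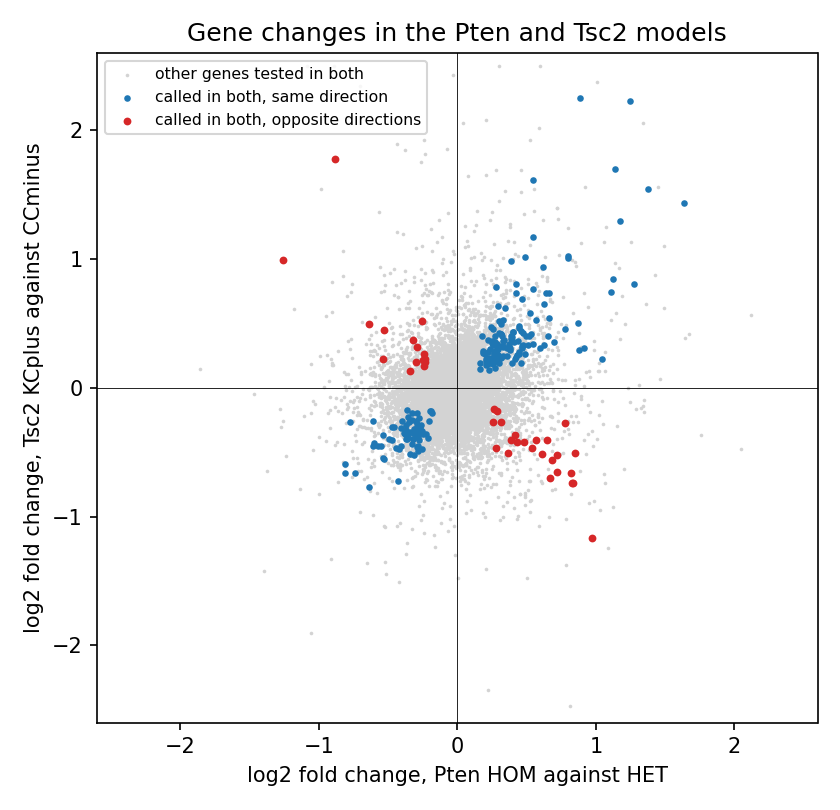
Log2 change of each gene tested in both models, Pten HOM against HET on the horizontal axis and Tsc2 KCplus against CCminus on the vertical axis, with genes called in both coloured by direction. There are 139 genes called higher in both and 68 called lower in both, with 39 called in opposite directions.

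The effect differed between the models for 535 of 14745 genes (278 more positive in Pten, 257 in Tsc2), where the kit, read length, age, dissection and kind of mutation also differed between the models. Nxph1 had log2 0.57 in Pten HOM and -0.40 in Tsc2 KCplus, a difference of 0.99 ± 0.102 (SE, adjusted p = 1.57e-05). S100b differed by 1.06, the deacetylase Sirt2 by 0.88, the GTPase Rnd2 by 0.80 and Tsc2 itself by 0.73. Tfrc differed by -1.41 (-0.06 and 1.36, adjusted p = 2.31e-06), the peptidase Dpp7 by -1.27, the hexokinase Hkdc1 by -1.12, Tmem181a by -0.97 and the proteasome activator Psme4 by -0.70. Of the 28 myelin genes 21 differed, all towards Pten (median 1.25, 24 adjusted over the list alone, adjusted p = 1.98e-21), as did 7 oligodendrocyte precursor genes (median 0.64, 12 adjusted over the list alone, adjusted p = 1.20e-09). Of the ATF4 genes 13 differed, all towards Tsc2 (median -0.37, 16 adjusted over the list alone, adjusted p = 5.81e-09). These 3 lists had adjusted p = 0.235, 0.157 and 0.113 with an estimated correlation, and 0 of the 13 lists that passed held with it. Immediate early genes passed as well with a sex term (adjusted p = 0.0278, adjusted p = 0.932 with an estimated correlation). Female libraries only gave 31 genes (12 and 19), and the count was 233 without KCplus replicate 3, 250 without CCminus replicate 2, 275 without CCminus replicate 3, 278 without KCplus replicate 1, 355 without CCminus replicate 4 and 950 without HOM replicate 2.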

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

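The tests of sex, of the dissected tissue and of the means of the lists were chosen only after the result was seen; the splits of the libraries were planned, and the tests of ribosomal protein genes were written after the data had been examined but before their own results were seen.

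The effect on myelin genes differed between the models, with a median log2 difference of 1.25 and 21 of 28 genes past the threshold of that test, and the effect on oligodendrocyte precursor genes with 0.64. Called in opposite directions were 4 myelin and 2 precursor genes, and the mean of the myelin list did not separate HOM from HET (exact permutation p = 0.0563). With an estimated correlation the difference had adjusted p = 0.235 for myelin and 0.157 for precursor genes, and myelin had 0.659 in the Pten and 0.537 in the Tsc2 model. A larger or smaller share of oligodendrocyte RNA in the piece dissected would move all members alike only if oligodendrocytes alone expressed them. Whether they do was not measured here. Beside the mean of the other members, in a limma fit on log2 CPM, 16 myelin genes differed between groups in the Pten model, Opalin, Gsn, Klk6 and Plp1 among them. In the Tsc2 model 7 did, among them Opalin, Cldn11 and Tspan2. Without that term 13 and 23 differed, but in edgeR, so the counts with and without it are not alike. The groups also held 31.5% (Pten) and 74.8% (Tsc2) of the variance of the list mean, so the term takes out part of any group difference. This test thus cannot tell a share of oligodendrocyte RNA from a change with genotype. Both stay open in both models, as do the models' different age, region and mutation.

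Ribosomal protein genes were lower in HOM than in HET and in KCplus than in CCminus (adjusted p = 0.427 and 0.548 with an estimated correlation), but against the 2 WT libraries their median was 0.03 in HOM and 0.25 in HET (adjusted p = 0.822 and 0.495 with an estimated correlation). Whether HOM stood low or HET high in the Pten model thus stays open. Lists of other genes matched on level and on gene length had medians at -18.1% (Pten) and -6.78% (Tsc2) of the ribosomal one, with 0 of 10000 lists as low. This argues against level and that length as the cause. The length was that of the gene in the Pten table, with a median of 1739 bp for the ribosomal list. Short transcripts as such were not tested. KCplus replicate 4, with 3.20% of its counts on ENSMUSG00000119584, an identifier without a name in the sources used here (CCminus 0.553% to 0.698%), was not the source either, since without it the median was 110% of the value with it (-0.33 against -0.30, 45 genes lower). Reads shared with pseudogenes, the lower mitochondrial share of HOM than of HET and a change with genotype stay open.

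The 871 genes between HOM and HET arose while HET was all female and HOM was mixed. Of the 500 leading genes of male HOM against 3 HET libraries, 95.3% moved the same way in female HOM against the other 3 (89.4% to 98.4% over 20 choices, 67.6% over all genes), and the cholesterol and ribosomal differences of female HOM were 108% and 107% of those of male HOM, which argues against sex as the whole cause. Male and female HOM (n = 3 each) differed in edgeR in the 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, with 141 of 14398 genes at an unadjusted p under 0.05. The 56 genes of female libraries lie within what other choices of 3 HOM libraries gave, 33 to 698 in the 18 mixed choices (median 166.5). They lie at the low end, as 4 of the 20 choices, the female one included, gave 56 or fewer. A part of sex in single genes may remain.

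The real split gave more genes than any other of 100 splits for HOM against HET (871, highest other 67). So it did among 35 splits for KCplus against CCminus (2232, highest other 1). This argues against chance only if each library came from a separate animal, which the labels do not say. For the Pten model the design text gives 4 HET and 4 HOM animals, fewer than the libraries, so there the condition may not hold. For the 207 genes shared between models the highest other split gave 0, but splits of the Tsc2 libraries that call at most 1 gene leave none to share, so they do not test overlap beyond chance. The 535 genes that differ between models were reached by 3 of 100 splits, the real one included, with 627 as the highest other. All but 4 of the other splits took away the real grouping of both models, so they do not test whether the effects are equal. The split with 627 kept the real Tsc2 grouping and a split with 552 kept the real Pten grouping, while the other 2 splits with the real Tsc2 grouping gave 74 and 47.

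Single genes differed between the models by a log2 of 1.06 for S100b, 0.99 for Nxph1, 0.88 for Sirt2, 0.80 for Rnd2 and 0.73 for Tsc2, and by -1.41 for Tfrc, -1.27 for Dpp7, -1.12 for Hkdc1, -0.97 for Tmem181a and -0.70 for Psme4. Lists differed by a median of 0.40 for reactive astrocytes (adjusted p = 0.00564, 0.0705 without CCminus replicate 2), 0.37 for disease-associated microglia (0.0072, 0.0507 without it), 0.34 for microglia, 0.22 for glutamate receptors, 0.21 for astrocytes (0.00274, 0.0507 without it), 0.16 for cholesterol synthesis and 0.11 for autism-associated genes (0.00564, 0.555 in female libraries only). With an estimated correlation these had adjusted p = 0.612 for reactive astrocytes and both microglia lists, 0.333 for glutamate receptors, 0.771 for astrocytes, 0.157 for cholesterol and 0.669 for autism-associated genes. They differed by -0.37 for the ATF4 response, -0.10 for lysosomal and -1.81 for choroid plexus genes (adjusted p = 0.113, 0.222 and 0.612 with an estimated correlation). Means of the choroid plexus list ran from -2.13 to 0.960 in HOM libraries and from -0.36 to 1.93 in KCplus libraries. Ribosomal genes differed by a median of 0.11 (adjusted p = 0.00287, adjusted p = 0.905 with an estimated correlation, no member past the threshold in edgeR), with 0.0551 without CCminus replicate 2 and 0.0629 without KCplus replicate 3.

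Sqle, Aacs and Dhcr24 stood apart in HOM replicate 2, at 129, 80.0 and 144 CPM where the other HOM libraries had 102 to 107, 69.7 to 73.4 and 175 to 182 (gap over range 0.815, 0.634 and 0.823). Opalin (19.9, others 23.7 to 24.3, ratio 0.873) and Rnf122 (9.76, others 12.9 to 13.5, ratio 0.838) stood apart in CCminus replicate 1, which also had the highest protein-coding share of its group (96.5%, ratio 0.831). HOM replicate 6 had the lowest total (14733320 counts, others 17234403 to 18619642, ratio 0.644) and HOM replicate 5 the highest mitochondrial share (5.27%, others 4.06% to 4.49%, ratio 0.642). Chance flags about 1 in 20 groups, and 8 of 98 stood apart here where 4.9 would by chance. WT replicate 1 held 950 Y-linked counts beside Xist, at 40.7% of the male and 84.5% of the female mean.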

How the results depend on the processing

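Female libraries only, and the sex term for gene lists, named genes and the models' comparison, were chosen after seeing the data; other alternatives were chosen before. The cause of a moved value was not tested, except that a stricter fold leaves fewer genes by construction. The HOM against HET count, 871, was 180 at 1.5-fold, 1492 with DESeq2 (871 shared), 324 with the replicate block, 108 with the sex term (107 shared), 56 in females (all shared) and 1313 with WT counted as HET. Leaving out 1 library gave 396 (HET replicate 3) to 1082 (HOM replicate 2), with 413, 437, 470 and 538 without HOM replicates 3 and 1 and HET replicates 5 and 2. The KCplus count, 2232, was 353 at 1.5-fold, 3381 with 1 surrogate variable, 1072 in females and 1363 (without KCplus replicate 3) to 2369 (without CCminus replicate 1), with 1394 without CCminus replicate 3. HOM against WT, 13, was 4 at 1.5-fold, 255 with DESeq2, 34 over all gene classes, 64 with 1 surrogate variable, 0 with the block, 1 with the sex term and 0 (without HOM replicate 1 or WT replicate 1) to 37 (without HOM replicate 2) per library left out. HET against WT, 0 in edgeR (367 at an unadjusted p under 0.05), was 4 with DESeq2 and 0 in edgeR whichever library was left out. The difference, 535, was 31 in females and 233 (without KCplus replicate 3) to 950 (without HOM replicate 2). The shared genes, 207, were 460 at an adjusted p under 0.1, 376 with DESeq2, 100 with the block, 37 with the sex term, 17 in females and 98 (without HET replicate 3) to 251 (without HET replicate 1). The correlation, 0.195, was 0.230 on ranks and 0.159 (without HOM replicate 2) to 0.229 (without CCminus replicate 2). In females it was 0.111 (exact permutation p = 0.3, where no value under 0.05 was possible). RLE size factors and no filter kept the 4 counts of HOM against HET, HOM against WT, KCplus and the difference within 1.5 times (859, 13, 2223, 542 and 734, 14, 2117, 447).

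Correlations of equal replicate numbers ran from -0.22 to 0.33 in the Pten and -0.07 to 0.41 in the Tsc2 model. The equal number was the best partner for 0 of 6 HET libraries, which gives no sign of a pairing in the Pten model but cannot exclude it. For CCminus the equal number was the best partner for 2 of 4 libraries, which leaves a pairing in the Tsc2 model open. Of 74 genes named for HOM against HET, all called except Pten, 74 kept their side of the threshold with DESeq2, 72 with RLE, 50 with the block, 28 with the sex term and 25 in females, and 728 of 888 results did with 1 library left out (Gria2, Ndufa3, Ccng2, Fcrls and Phgdh lost their call in 10 or 11). Of 119 for KCplus, 118, 119, 119, 112 and 96 did, and 876 of 952. Lists kept their call with RLE in all 12 (HOM against HET) and 15 (KCplus) cases, in 12 and 14 with the block (glutamate receptors 0.0580 in KCplus; against WT the block gave 0.589 for astrocyte and 0.271 for pan-neuronal genes in HET and 0.109 for myelin genes in HOM), and in 1 and 1 with an estimated correlation. The direction reversed for HET against WT in myelin genes without WT replicate 1 (adjusted p = 0.949, range over libraries left out from 0.000312 without HET replicate 4) and in endothelial genes with the block (0.730) and the sex term (0.985). At 14733320 to 18621342 counts the simulated HOM against HET libraries gave 64 of 100 genes changed 1.5-fold, and at 18365289 to 25097344 the simulated Tsc2 libraries gave 79.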

Other observations

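The tests of list means per library were chosen only after the result was seen, and the genes named here were chosen after their values were seen. Beyond lipid and neurofilament genes, the models shared called changes in further genes, most of them outside the lists. The desmosomal Dsc3 (log2 1.63 in Pten HOM, 1.44 in Tsc2 KCplus), the myosin Myh4 (1.37 and 1.55), the reductase Akr1c18 (1.24 and 2.23), Srpx2 (1.14 and 1.70), Pdlim3 (1.17 and 1.29), the hormone gene Stc1 (1.12 and 0.85), Mybpc1 (0.89 and 2.25), the protease Bace2 (0.66 and 0.73), the peptide gene Pnoc (0.62 and 0.94), the haem oxygenase Hmox1 (0.55 and 1.17) and Pik3r3 (0.47 and 0.69) rose in both. Lower in both were the kinase Etnk2 (-0.74 and -0.66), Sned1 (-0.64 and -0.77), the clock gene Per3 (-0.55 and -0.45), Tspoap1 (-0.57 and -0.45), the proline-degrading Prodh (-0.54 and -0.54), the cortical transcription factor Emx2 (-0.61 and -0.45), the kinase inhibitor Camk2n1 (-0.44 and -0.47) and the serine-synthesising Phgdh (-0.33 and -0.44). With a sex term 37 genes and in female libraries only 17 were shared. The Pearson correlation of the effects did not pass (exact permutation p = 0.0857), while that on ranks had the smallest possible p of this permutation (0.0286).

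Opposite in the models were the oligodendrocyte genes Padi2 (0.82 and -0.74), Ugt8a (0.85 and -0.50), Gjc2 (0.67 and -0.70), the myelin proteolipid Plp1 (0.69 and -0.56) and Olig2 (0.43 and -0.42). So were the peptide gene Cort (-0.88 and 1.77) and the collagen Col24a1 (-1.26 and 0.99).

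The mean of a list per library separated HOM from HET completely for 5 lists (two-sided exact permutation p = 0.00216, adjusted p = 0.0147). These were cholesterol (0.35 ± 0.0568, SD, n = 6), lysosomal (0.10 ± 0.0393), ribosomal (-0.22 ± 0.0995), disease-associated microglia (0.33 ± 0.0772) and pan-neuronal genes (0.18 ± 0.0704). In the Tsc2 model 11 lists reached the smallest exact permutation p of 0.0286 (adjusted p = 0.0883), among them lysosomal (0.21 ± 0.0124, n = 4), ATF4 (0.31 ± 0.133), ribosomal (-0.30 ± 0.105) and myelin genes (-0.60 ± 0.231).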
